A study of Mus musculus with 15 samples.

How the data were processed

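The series holds RNA sequencing of bone marrow cells sorted as LSK, a lineage-negative fraction with Sca1 and cKit on its surface that is enriched for blood stem and early progenitor cells. Per the labels, the mice were C57BL/6 and the RNA went into stranded mRNA libraries. The genotype labels give 5 groups of 3 libraries, 15 in all: wild type (WT), Tet2-/-, Nras(G12D), Tet2-/- Nras(G12D) animals without leukemia (called the double mutant from here on) and Tet2-/- Nras(G12D) animals with leukemia (the leukemic double mutant). The design text names an age of 6 months for the animals whose methylome was examined. Nothing in the labels says that the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may in part be technical. The column names were matched to samples by the description label of each sample. The column N2-3 was taken as library 2 of Nras(G12D), and the BMT columns as the leukemic libraries with the same numbers. Of the 5 groups only the leukemic one is described with BMT (as TN-BMT), and what BMT stands for was not established here. Whatever it marks cannot be told apart from leukemia in these data.

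The authors' table gives 1 value per gene symbol and library for 44827 genes. The deposited values are on a log2 scale: log2 CPM (a gene's count relative to its library size) with 0.5 added to each gene's count and 1 to the library size. This unit was read from the values, since under that formula 100% of them come back as whole counts within a tolerance of 1e-06. The library size behind each deposited column differed from the sum of its counts by a factor of 0.81 to 1.12, so a scaling factor per library is part of the authors' log2 values. No filter on low genes had been applied: 11321 genes had 0 counts in every library. Per the submitters' processing notes, bcl2fastq, STAR 2.4.0f1, edgeR 3.14.0 and limma 3.28.21 were used, and the builds mm10 and NCBIM37 are named without a role. The counting tool, its annotation and whether strand was used in counting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies may have been assigned to either gene.

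Total counts recovered per library ran from 22733189 to 43562909. A gene with 0 counts in a library is limited to 3 counts, or 0.0775 to 0.127 CPM, which covers counting error only.

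Genes with at least 1 CPM in at least 3 libraries were tested, 13927 of them. The deposited log2 values were fitted with limma 3.58.1 (lmFit, contrasts.fit, eBayes with an intensity trend) in R 4.3.3, with a mean for each of the 5 groups and all 15 libraries in 1 fit, which leaves 10 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p below 0.05 was called. The comparisons were 7 pairs of groups, the interaction (double mutant minus Tet2-/- minus Nras(G12D) plus WT) and an F test over all groups. Fold changes are on the log2 scale with the added 0.5 count, which understates changes of low genes. Values are given as mean ± SD in CPM and log2 changes as estimate ± standard error, with n = 3 per group. The fit was tested on simulated data of all 13927 genes. Known changes were put into a small part of them, and each gene had the same spread in every library. In the comparison of Tet2-/- with WT the fit recovered 10% of genes changed by a log2 of 1, 66.1% of those changed by 2 and 91.5% of those changed by 3. For Nras(G12D) the shares were 17.3%, 71.6% and 89.2%, for the double mutant 13.9%, 73.9% and 94.9%, and for the leukemic double mutant 12.7%, 56.7% and 91%. Real libraries differed in spread, and 3443 genes were called in the leukemic double mutant against WT. The simulated shares need not hold for such data.

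The rule for named genes was fixed before the data were examined, as were the groups, tests, gene lists and the alternatives listed first below. It takes, per comparison, up to 10 rises and 10 falls of largest log2 size among called genes whose 3 values in 1 group all lie above those of the other and whose mean in the higher group is at or above the median of tested genes (log2 CPM 4.65), leaving out unnamed models, pseudogenes, antigen receptor segments and mitochondrial genes. Tet2, Nras, Spry2 and Dusp6 are always named, and up to 4 members per list, those of smallest adjusted p. A gene named outside this rule is said to be so, and some genes that the rule names are not reported here.

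There were 24 gene lists: haematopoietic stem cell, lymphoid priming, granulocyte-monocyte progenitor, mature neutrophil, monocyte and macrophage, dendritic cell and antigen presentation, erythroid, megakaryocyte and platelet, mast cell basophil and eosinophil, B cell, T and NK cell, and stromal and endothelial genes; ERK output and feedback genes, RAS pathway components, DNA methylation machinery, S phase and mitosis genes, cell cycle inhibitors, interferon-stimulated genes, NF-kB and inflammatory cytokine genes, leukaemic self-renewal genes, p53 targets, glycolysis genes, and immediate early and dissociation stress genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over all 192 tests. Camera with a correlation estimated from the residuals and limma's fry, which asks whether a list moves one way and does not compare it with other genes, were alternatives. Camera called 72 of the 192 tests, none of them with an estimated correlation, and 14 of the 72 were called by fry. Most list members are also expressed in WT LSK cells: 22 of 22 stem cell genes, 20 of 21 erythroid genes, 14 of 16 dendritic cell genes and 16 of 19 immediate early genes had a mean of at least 1 CPM there. Of the 19 immediate early genes, 3 also belong to another list.

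Overlaps between comparisons against WT were set beside the product of the list lengths and beside 100 simulations of unchanged groups that share their WT libraries, where as many genes as were called were taken per direction from the top of each comparison. Only a minimum log2 change of 1 had been set for them before the data were examined; the other alternatives that fit all groups at once were added afterwards. The alternatives were other filters, fits with only the compared groups, the replicate number as a block, quantile normalization, median centring, a fit without the trend, array weights, a minimum log2 change of 1, and leaving out each library in turn. Added after the data were seen were voom weights, voom with sample quality weights, array weights estimated gene by gene, an added count of 0.1 in place of 0.5, scaling by total counts and by median of ratios, Y-linked expression as a covariate, and a correction for GC content and length (97.7% of tested genes had both), alone or with the block. The labels do not say what the replicate numbers mark. Same-numbered libraries of Tet2-/- and the double mutant deviated together from their group means, with correlations across genes of 0.14, 0.11 and 0.12. Those between different numbers were -0.01 or lower, but deviations cancel out within a group, which favours such values. For that comparison, picked by these correlations, the block was read as a possible pairing. The correlations are too small to settle it, and WT 1 with Nras(G12D) 3, of different numbers, had 0.47. Coordinates are from the GENCODE annotation of GRCm38, matched by symbol (97.9% of symbols); the table itself has none. The methylome named in the design text was not analysed here.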

Results

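Gene expression in sorted LSK cells was measured in 5 groups of 3 libraries: WT mice, mice lacking Tet2, mice with the activating Nras(G12D) mutation, double mutant mice without leukemia, and leukemic double mutant mice. The series title names the joint effect of Tet2 loss and mutant Nras on myeloid transformation. Each mutant was therefore set against WT, the double mutant against each single mutant, and the leukemic against the non-leukemic double mutant. Total counts were 23821717, 24629195 and 26079674 in the WT libraries 1 to 3, and 22733189, 32543558 and 32761321 in Tet2-/-. They were 24242814, 43562909 and 29979446 in Nras(G12D), 27152151, 33037109 and 27160858 in the double mutant, and 30256895, 37363121 and 36343412 in the leukemic double mutant. Correlations of log2 CPM across genes between libraries of 1 group ran from 0.908 to 0.974. No 2 libraries of a group matched within sampling noise, the lowest chi-square per degree of freedom being 23.3. The first principal component held 42% of the variance and the next 18.8%. Leukemic libraries 2 and 3 lay at 146.6 and 113.6 on the first, leukemic library 1 at 51.6, and the other 12 libraries between -105.2 and 22.6.

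The targeted genes were read first. Tet2, a dioxygenase that oxidises methylated cytosine, lies on chromosome 3 of GRCm38 (133463679 to 133545139, minus strand). It was at 65.2, 50.7 and 61 CPM in the WT libraries, 35.9, 59.8 and 49.3 in Tet2-/-, and 56.8, 45.2 and 75.1 in Nras(G12D). In the double mutant it was at 62.6, 56.3 and 47.9 CPM, and in the leukemic double mutant at 76.5, 32.3 and 39. The gene total passed the limma threshold in none of the 7 comparisons of 2 groups. The labels do not say which part of Tet2 is deleted, so a total over the gene need not follow the deletion. Nras (chromosome 3, 103058285 to 103067914, plus strand) was at 179, 172 and 167 CPM in WT, 247, 185 and 282 in Tet2-/-, and 153, 200 and 191 in Nras(G12D). It was at 159, 157 and 145 CPM in the double mutant and at 165, 196 and 161 in the leukemic double mutant. Its only call was between the double mutant and Tet2-/-, a log2 change of -0.61 ± 0.19 (limma, adjusted p = 0.0292). That Nras call was lost without Tet2-/- 1 (-0.57), Tet2-/- 3 (-0.48), double mutant 1 (-0.64), double mutant 2 (-0.63) or double mutant 3 (-0.57), after quantile normalization (-0.46) and with no filter. A single codon change cannot be read from gene totals.

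Libraries of the same group also differed in sex-linked genes. Ddx3y, on the Y chromosome, was at 259 and 179 CPM in Tet2-/- libraries 1 and 2, 91.5 in Nras(G12D) 2, 175 in double mutant 1 and 157 in leukemic 1. It was at or below 0.476 CPM in the other 10 libraries. Xist, expressed from the inactive X chromosome, was at or below 0.709 CPM in those 5 libraries except leukemic 1, which had 56.8. The WT libraries had Xist at 490, 433 and 366 CPM, so by these genes WT holds 1 sex and each mutant group is mixed.

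Loss of Tet2 alone came with few called changes. Gbp2b, an interferon-inducible GTPase gene, rose by a log2 of 8.83 ± 1.04 in Tet2-/- over WT (limma, adjusted p = 0.00196), from 0.145 ± 0.077 to 64.4 ± 31.5 CPM (SD, n = 3). H2-Aa, an MHC class II chain, rose from 76.1 ± 22.6 to 591 ± 349 CPM (log2 2.81 ± 0.53, adjusted p = 0.0486). Lgals3, which encodes galectin-3, rose by 2.39 ± 0.39, the chemokine receptor gene Ccr2 by 2.04 ± 0.37, Alpk1, an innate immune kinase, by 2.26 ± 0.42 and Gcsam by 1.87 ± 0.26. Thbs1, which encodes thrombospondin-1, fell by 6.73 ± 0.76 on the log2 scale, to 1.98 ± 0.943 CPM from 304, 77.2 and 302 in the WT libraries. The basophil protease gene Prss34 fell by 3.58 ± 0.55, Manf fell by 1.94 ± 0.36 and the ribosomal protein gene Rpl34 fell by 1.48 ± 0.24. Gbp2b, Alpk1 and Rpl34 lie near Tet2 on chromosome 3. A strain haplotype kept around the targeted locus was not excluded for them, so their changes need not follow from Tet2 loss. In all 15 genes rose and 17 fell (Benjamini-Hochberg adjusted p below 0.05), with 3304 at an unadjusted p below 0.05. Quantile normalization gave 95 rises and 49 falls, median centring 60 and 29, and scaling by total counts 10 and 18. Changes also followed GC content across genes (Spearman -0.31), and the GC and length correction gave 24 rises and 24 falls. Voom with sample quality weights gave 3388 rises and 3550 falls, so the low count depends on giving each library the same weight. The count was 5 without WT 1, 6 without WT 2, 8 without WT 3, 54 without Tet2-/- 1, 2235 without Tet2-/- 2 (408 higher and 1827 lower) and 13 without Tet2-/- 3. Of the 10 genes above only Gbp2b and Thbs1 were called without each library. Gcsam and Prss34 lost their calls without WT 1 (1.81 and -3.68) or WT 2 (1.71 and -3.19). The other 6 lost theirs without any 1 of the WT libraries, and H2-Aa (2.37), Lgals3 (1.94), Ccr2 (1.55), Alpk1 (2.02) and Manf (-1.77) also without Tet2-/- 3. Rpl34 (-1.39), Alpk1 (2.14) and Manf (-1.61) were also lost without Tet2-/- 1. Scaling by total counts ended the calls of H2-Aa, Ccr2 and Alpk1, and an added count of 0.1 those of H2-Aa and Manf.

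Dendritic cell and antigen presentation genes had a median log2 change of 2.1 in Tet2-/-, with 14 of 16 above 0. H2-Aa alone passed over all genes, while 10 rose and 1 fell adjusted over the list alone. Erythroid genes had a median of -1.92, with none of 21 past the threshold and 6 lower adjusted over the list alone. Klf1, the erythroid master regulator, was at 0.893 ± 0.866 CPM against 11 ± 6.43 in WT. Interferon-stimulated genes had a median of 0.56, with 26 of 30 above 0, none past the threshold by either count, and a median of 0.19 without Tet2-/- 3. The camera adjusted p-values of these 3 lists were 3.87e-06, 0.00103 and 0.00187. With an estimated correlation their adjusted p-values were 0.771, 0.771 and 0.783. Mature neutrophil genes (median 0.72, camera adjusted p = 0.0412) and NF-kB and inflammatory cytokine genes (0.61, 0.0451) had adjusted p = 0.809 and 0.771 with an estimated correlation. The first call was lost without WT 3 or any 1 of the Tet2-/- libraries (medians from 0.52 to 1.04) and the other without WT 1 (0.6) or Tet2-/- 2 (0.77). Mitosis genes had a median of -0.14 (camera adjusted p = 0.0408, adjusted p = 0.809 with an estimated correlation), which was 0.05 without Tet2-/- 1, and the call was lost without WT 3 (-0.18), Tet2-/- 1 or Tet2-/- 2 (-0.11). Without Tet2-/- 3 the mitosis median was -0.43. The 17 genes of the DNA methylation machinery had a median of -0.31 and none past the threshold (camera adjusted p = 0.254).

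Nras(G12D) alone gave no called gene against WT. Limma found 0 genes past the threshold and 577 at an unadjusted p below 0.05, voom weights gave 2 and a fit with only the compared groups 1. Leaving out Nras(G12D) 3 gave 5. Haematopoietic stem cell genes lay lower in Nras(G12D), all 22 of them below 0 with a median log2 change of -0.79, and of -0.52 without Nras(G12D) 2. Mecom, a stem cell transcription factor chosen after its values were seen, was at 52.2 ± 13.7 CPM against 114 ± 22.6 in WT (n = 3). ERK output and feedback genes, which report signalling below RAS, had a median of 0.58 with 17 of 21 above 0. The feedback inhibitor Spry2 was at 4.55 ± 1.77 against 2.28 ± 0.426 CPM and the phosphatase gene Dusp6 at 214 ± 79.6 against 161 ± 32.8. Dendritic cell and antigen presentation genes had a median of 1.14, and of 1.79 without Nras(G12D) 2. Mature neutrophil genes had a median of 1.05, but of -0.42 without Nras(G12D) 2, where the call was lost, of 1.75 without Nras(G12D) 1 and of 1.81 without Nras(G12D) 3. The camera adjusted p-values of these 4 lists were 1.48e-06, 0.000653, 3.53e-06 and 0.000268, and each adjusted p was 0.771 with an estimated correlation. None had a member past the threshold over all genes, and adjusted over the list alone only the dendritic cell list did, with 2 higher and 1 lower.

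In the double mutant without leukemia, immediate early genes stood highest among the lists. Jun rose from 35.5 ± 21.4 CPM in WT to 1080 ± 638 in the double mutant (limma, log2 4.89 ± 0.77, adjusted p = 0.0129, n = 3). Fos rose from 33.3 ± 5.55 to 722 ± 245 (4.39 ± 0.88, adjusted p = 0.0382), and Egr1 from 8.77 ± 3.16 to 178 ± 13.1 (4.4 ± 0.64, adjusted p = 0.0104). These genes encode transcription factors induced within minutes of a stimulus. The phosphatase gene Dusp1 rose by a log2 of 4.92 ± 0.73, Ier5 by 4.03 ± 0.68 and Jund by 4.01 ± 0.71. Of 19 immediate early genes 10 rose, or 16 adjusted over the list alone, and none fell (median 3.32, camera adjusted p = 3.86e-15, fry adjusted p = 0.0142). With an estimated correlation the camera adjusted p was 0.581. Camera at the preset correlation also called this list against WT in Nras(G12D) and in the leukemic double mutant. Leaving out 1 library gave medians of 0.27 to 0.58 in Nras(G12D), the call being lost without Nras(G12D) 2 or 3. In the leukemic double mutant they were 0.02 to 1.3, the call being lost without leukemic 3. Heat shock genes, chosen after their values were seen and also induced by handling, moved apart. Hspa1a was at a log2 of 3.75 ± 1.06, Hspa1b at 3.32 ± 1.19 and Dnajb1 at 0.44 ± 0.46. Hspa8 was at -0.38 ± 0.27 and Hsph1 at -0.71 ± 0.53, and none of them passed the threshold. Dendritic cell and antigen presentation genes rose in 5 of 16 cases and in 13 adjusted over the list alone, where 1 fell. H2-Aa rose by 2.81 ± 0.53, the MHC class II regulator gene Ciita by 2.5 ± 0.52, Itgax by 2.33 ± 0.47 and Cd209a by 3.65 ± 0.75 (list median 2.55, camera adjusted p = 1.38e-08). That list had an adjusted p = 0.771 with an estimated correlation.

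Other named rises in the double mutant over WT were Gbp2b (log2 7.7 ± 1.04), Plbd1 (3.89 ± 0.73), the MYC family gene Mycl (3.89 ± 0.81) and Ifi205 (3.48 ± 0.71). Thbs1 fell by 7.17 ± 0.76, Igf2r fell by 2.54 ± 0.45, Abcg3 fell by 2.46 ± 0.47 and the circadian gene Arntl fell by 1.44 ± 0.28. Rpl34 fell by 1.35 ± 0.24. Of 21 ERK output genes Egr1 and Fos rose, and 7 did adjusted over the list alone (median 0.92). Spry2 was at 6.32 ± 0.675 CPM against 2.28 ± 0.426 in WT and Dusp6 at 241 ± 26.4 against 161 ± 32.8, neither past the threshold. Among 13 cell cycle inhibitors Btg1 (2.47 ± 0.4), Btg2 (1.79 ± 0.31) and Cdkn2c (1.92 ± 0.41) rose, and 4 did adjusted over the list alone (median 0.67). B cell genes went both ways, with Cd22 higher by 3.62 ± 0.6 and Bank1 lower at -2.5 ± 0.48, and 1 higher and 5 lower adjusted over the list alone. Their median was -0.63, with -1.11 without double mutant 1 and -0.36 without double mutant 3. The camera adjusted p-values of these 3 lists were 2.54e-05, 0.000653 and 0.00916, and with an estimated correlation their adjusted p-values were 0.771, 0.581 and 0.771. Lymphoid priming genes had a median of -0.5, or -0.08 without double mutant 3, with 3 of 16 lower adjusted over the list alone. Glycolysis genes had a median of -0.32, with 1 of 19 above 0 and none past the threshold. For the latter pair the camera adjusted p was 0.0127 and 0.00104, and each adjusted p was 0.771 with an estimated correlation.

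Across the transcriptome 68 genes rose and 27 fell in the double mutant against WT (limma, 95 in all), and 2119 had an unadjusted p below 0.05. This count was 6 without WT 1, 34 without WT 2, 9 without WT 3, 992 without double mutant 1, 14 without double mutant 2 and 12 without double mutant 3. Of the 16 genes named by size, only Thbs1 was called in each of these fits. Egr1 lost its call without WT 1 (log2 4.15) and WT 3 (4.38), and Jun without WT 1 (4.37), WT 3 (4.95), double mutant 2 (4.67) and double mutant 3 (4.47). Gbp2b lost it without WT 1 (7.13) and Cd22 without WT 1 (3.51), WT 3 (3.59) or double mutant 2 (3.44). The other genes named as risen or fallen against WT lost theirs without each of WT 1, WT 3, double mutant 2 and double mutant 3. Scaling by total counts ended the calls of Ciita, Itgax, Mycl and Ifi205, and an added count of 0.1 those of Cd209a and Cdkn2c. With the Y-linked genes as a covariate the count was 396, with only the compared groups 574 and with quantile normalization 213.

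**Figure D1:**
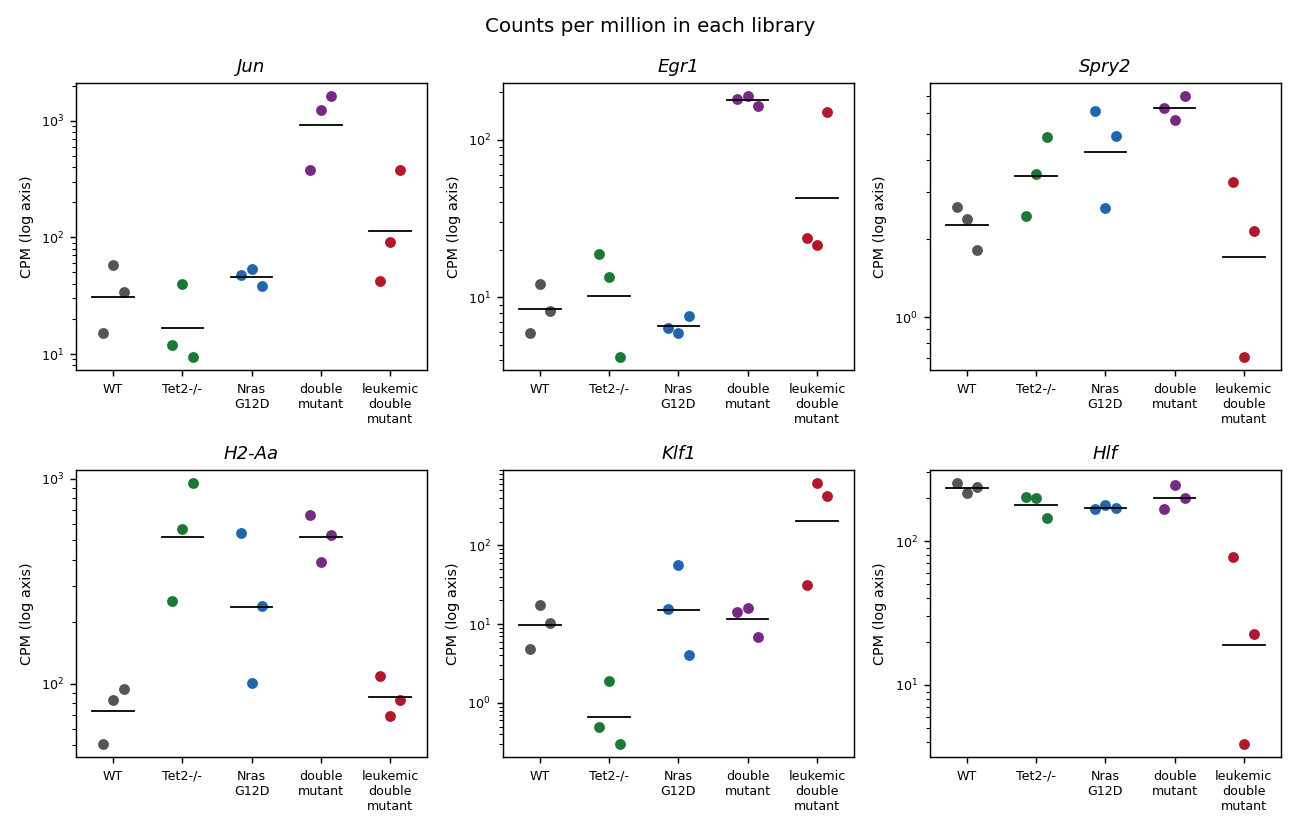
CPM (log axis) of Jun, Egr1, Spry2, H2-Aa, Klf1 and Hlf in each library, where points are libraries and black lines geometric means of 3. Egr1 lay between 163 and 189 CPM in the double mutant libraries and at or below 12.2 in WT, and Klf1 reached 620 and 419 CPM in leukemic libraries 2 and 3.

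Adding mutant Nras to Tet2 loss, the double mutant against Tet2-/-, again gave higher immediate early genes. Jun rose by a log2 of 5.78 ± 0.77 (limma, adjusted p = 0.00472), Dusp1 by 5.19 ± 0.73 and Jund by 5.02 ± 0.71, and 13 of 19 rose, or 14 adjusted over the list alone (median 3.86). RAS pathway components rose in 13 cases and fell in 1 of 30, and adjusted over the list alone 16 rose and 3 fell (median 1.09). The MEK genes Map2k2 (3.19 ± 0.57) and Map2k1 (2.29 ± 0.48) were among the risen. Cell cycle inhibitors rose in 7 of 13, as many adjusted over the list alone (median 1.06). ERK output genes rose in 7 of 21, or 9 adjusted over the list alone (median 1.27, and 0.77 without Tet2-/- 1). The camera adjusted p-values of these 4 lists were 4.42e-06, 0.00731, 0.00421 and 0.00364, and with an estimated correlation their adjusted p-values were 0.771, 0.771, 0.64 and 0.771. Interferon-stimulated genes fell in 6 of 30 by both counts (median -0.83), and glycolysis genes fell in 9 of 19 and rose in 1, or in 3 adjusted over the list alone (median -0.45). Rsad2 fell by 1.47 ± 0.4, a call lost without Tet2-/- 1 (-1.47), Tet2-/- 3 (-1.25) or double mutant 3 (-1.03), and Gapdh fell by 0.85 ± 0.17. For these 2 lists the camera adjusted p was 9.68e-05 and 0.0164, and each adjusted p was 0.771 with an estimated correlation.

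Lymphoid priming genes fell in 4 and rose in 1 of 16 by both counts, and camera did not call the list (median -0.88, adjusted p = 0.176, and adjusted p = 0.809 with an estimated correlation). Dntt, the terminal transferase of early lymphoid progenitors, fell by 2.27 ± 0.56, from 1170 ± 270 CPM in Tet2-/- to 280 ± 165 in the double mutant. Its call was lost without Tet2-/- 3 (-2.1) or double mutant 3 (-1.64). The Notch effector gene Rbpj fell by 1.6 ± 0.26. Other rises were Hist1h2ae (5.59 ± 1), Ppp1r35 (5.2 ± 0.88), Abhd17a (4.77 ± 0.78) and the transcription factor gene Sox4 (4.7 ± 1.02), which was at 14.8, 187 and 262 CPM in the double mutant libraries. The DNA methylation machinery rose in 8 of 17, p53 target genes in 5 of 20 and leukaemic self-renewal genes in 9 of 28 with 1 fall, the same counts adjusted over the list alone. Camera called none of these lists (adjusted p = 0.111, 0.256 and 0.303). Megakaryocyte and platelet genes rose in 6 of 19 by both counts (median 0.59, camera adjusted p = 0.101). NF-kB and inflammatory cytokine genes rose in 6 and fell in 1 of 24 by both counts, with a median of -0.02 but a mean of 0.37 (camera adjusted p = 0.796). Such counts stand beside 2806 rises and 1193 falls in all 13927 tested genes, so any list would hold some called members. Of the called genes 70.2% were higher, and 5977 tested genes had an unadjusted p below 0.05. The share was 45.9% after quantile normalization (2327 and 2746), 33.3% after median centring (2020 and 4039) and 56.5% after the GC and length correction (2327 and 1789). The mean library median was 4.4 log2 CPM in Tet2-/- and 4.87 in the double mutant. The count was 1258 without Tet2-/- 1, 1595 without Tet2-/- 3, 1663 without double mutant 2 and 1439 without double mutant 3.

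Adding Tet2 loss to mutant Nras gave few called genes. Egr1 rose by a log2 of 4.74 ± 0.64 in the double mutant over Nras(G12D) (limma, adjusted p = 0.0051), from 6.66 ± 0.83 to 178 ± 13.1 CPM (n = 3). Gbp2b rose by 9.27 ± 1.04 and Rpl34 fell by 1.81 ± 0.24. The latter 2 genes lie near Tet2 on chromosome 3, where a strain haplotype kept around the targeted locus was not excluded. Immediate early genes had a median of 2.5, with 1 of 19 past the threshold over all genes and 16 higher adjusted over the list alone. Their camera adjusted p was 2.41e-15 and their fry adjusted p 0.0281, with a camera adjusted p = 0.581 with an estimated correlation. Erythroid genes had a median of -1.21, or -0.69 without Nras(G12D) 1 or double mutant 3, and T and NK cell genes one of -1.01, or -0.67 without double mutant 3. Neither had a member past the threshold by either count. The camera adjusted p was 0.000193 and 0.000503 for this pair, and each adjusted p was 0.771 with an estimated correlation. In all 7 genes rose and 4 fell, with 1032 at an unadjusted p below 0.05. Quantile normalization gave 11 and 14, and median centring 8 and 9. Without double mutant 1 there were 114 genes. The interaction asks whether the double mutant departs from the sum of the single mutants' changes. Limma called 0 genes there (2924 at an unadjusted p below 0.05), voom weights 0, voom with sample quality weights 5917 and array weights 6639. The interaction called 1692 genes without Tet2-/- 2, 505 without double mutant 1 and 1 without double mutant 2.

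The leukemic libraries differed from WT in more genes than the other mutant groups did, with erythroid genes higher and stem cell genes lower. Of 21 erythroid genes 17 rose, or 20 adjusted over the list alone, and none fell (median log2 change 2.95, camera adjusted p = 4.81e-09, fry adjusted p = 0.0274), with an adjusted p = 0.771 with an estimated correlation. Rhag, an erythroid membrane protein gene, rose by 4.81 ± 0.78 (limma, adjusted p = 0.0022), the erythropoietin receptor gene Epor by 3.52 ± 0.61 and Gata1 by 2.62 ± 0.51. Klf1 rose by 4.38 ± 1.09, with 31.1 CPM in leukemic library 1 and 620 and 419 in libraries 2 and 3. It lost its call without WT 1 (3.89), leukemic 2 (3.57) or leukemic 3 (3.85). Of 22 stem cell genes 12 fell, or 14 adjusted over the list alone, and none rose (median -2.1, or -1.33 without leukemic 2, camera adjusted p = 4.22e-05). The stem cell list too had an adjusted p = 0.771 with an estimated correlation. Hlf, a stem cell transcription factor, went from 236 ± 18.6 CPM in WT to 77.5, 3.9 and 22.7 in the leukemic libraries, and Procr fell by 3.48 ± 0.66. Of the surface proteins of the LSK gate, Kit was at 499 ± 156 CPM against 1240 ± 158 in WT and Ly6a, which encodes Sca1, at 123 ± 62.5 against 88.1 ± 14.8 (n = 3).

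Lists of other lineages moved less in the leukemic double mutant against WT. Mast cell, basophil and eosinophil genes rose in 5 of 17 by both counts (median 0.91), and B cell genes fell in 4 of 16, or 5 adjusted over the list alone (median -1.22). Their camera adjusted p was 0.0368 and 0.0127, and each adjusted p was 0.771 with an estimated correlation. The mast cell call was lost without WT 3, leukemic 1 (0.64) or leukemic 3, with a median of 1.51 without leukemic 2, and the B cell call without leukemic 2 (-0.69). Stromal and endothelial genes fell in 3 of 8 by both counts (camera adjusted p = 0.206). Granulocyte-monocyte progenitor genes rose in 3 and fell in 2 of 22, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.238). Monocyte and macrophage genes rose in 3 and fell in 2 of 21, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.472). S phase genes rose in 5 of 22 by both counts, with Ccne1, which encodes cyclin E1, at 3.49 ± 0.56 (median 0.64, camera adjusted p = 6.9e-05, fry adjusted p = 0.0423). That list too had an adjusted p = 0.771 with an estimated correlation. Among 28 leukaemic self-renewal genes 2 rose and 5 fell by both counts, including Meis1 (-2.56 ± 0.51) and Erg (-2.14 ± 0.48), both stem cell transcription factor genes (camera adjusted p = 0.224).

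Further rises in the leukemic double mutant over WT were Rnf128 (log2 6.61 ± 1.02), Podxl (4.97 ± 0.88), the metallothionein gene Mt2 (4.76 ± 0.82), the matrix protease gene Mmp14 (4.37 ± 0.65) and Emilin2 (4.34 ± 0.55). Falls were Myl10 (-6.14 ± 0.96), Thbs1 (-6.04 ± 0.76), Slc16a12 (-5.33 ± 0.81), Abcg3 (-4.98 ± 0.47), Als2cl (-4.59 ± 0.6) and Trpc6 (-4.56 ± 0.63). In all 1505 of the 13927 tested genes rose and 1938 fell, and the counts of list members above stand beside these. An unadjusted p below 0.05 was found for 5461 genes. Scaling by total counts gave 974 and 2789, while rises outnumbered falls with only the compared groups (1487 and 1202) and with the stricter filter (1162 and 983). The count was 1356 without WT 1, 1629 without WT 3, 5251 without leukemic 1, 1469 without leukemic 2 and 1855 without leukemic 3. Of the 20 genes named by size, 19 were called in each of these fits. Cma1, a mast cell chymase gene with a log2 change of 5.93, lost its call without WT 3 (4.4).

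Leukemic against non-leukemic double mutants, the comparison of overt disease with the same genotype label without it, gave erythroid genes higher and immediate early, ERK output and antigen presentation genes lower. The leukemic samples alone also carry BMT in their descriptions, and what that marks cannot be separated from disease here. Rpl34, called lower than WT in Tet2-/- and the double mutant, was at 50.41, 47.11 and 57.84 CPM in the double mutant libraries. It was at 141.61, 192 and 196.5 CPM in the leukemic libraries and at 144.68, 143.61 and 109 in WT. A difference in genotype or a wrong label was therefore not excluded for this comparison. Of 21 erythroid genes 18 rose, or 19 adjusted over the list alone, and none fell (median log2 change 4.12). The globin genes Hbb-bs (6.97 ± 1.29, at 21.2, 334 and 31.2 CPM in the leukemic libraries) and Hba-a1 (6.1 ± 1.03) rose, as did Rhag (6.13 ± 0.78). Dendritic cell and antigen presentation genes fell in 12 of 16 by both counts, with 1 higher adjusted over the list alone, and with Cd209a at -5 ± 0.75 and H2-Aa at -2.59 ± 0.53 (median -2.34). S phase genes rose in 14 of 22 by both counts, with Ccne1 at 2.81 ± 0.56 (median 0.88). Glycolysis genes rose in 8 of 19, or 11 with 1 fall adjusted over the list alone, with Ldha at 1.37 ± 0.19 (median 0.7). The camera adjusted p-values of these 4 lists were 5.44e-13, 0.000858, 1.22e-07 and 0.000264, and each adjusted p was 0.771 with an estimated correlation. Stem cell genes fell in 12 and rose in 1 of 22, or 13 and 2 adjusted over the list alone, with Hlf at -3.4 ± 0.69 (median -1.81, or -2.79 without leukemic 1 and -1.13 without leukemic 2). Their camera adjusted p was 0.00494, with an adjusted p = 0.797 with an estimated correlation.

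Immediate early genes fell in 11 of 19 in this comparison, or 12 adjusted over the list alone (median -2.06, camera adjusted p = 0.00179, and adjusted p = 0.771 with an estimated correlation), and lost the call without leukemic 1 (-1.64). ERK output genes fell in 10 of 21, or 11 adjusted over the list alone (median -1.31, camera adjusted p = 0.0224, and adjusted p = 0.771 with an estimated correlation), and lost the call without leukemic 2 (-0.94). Spry2 fell by 1.89 ± 0.5 (limma, adjusted p = 0.0169), to 2.04 ± 1.29 CPM, and Dusp6 fell by 2 ± 0.62 (adjusted p = 0.033), to 70.7 ± 45.7 CPM. The Spry2 call was lost without double mutant 3 (-1.81) or leukemic 2 (-1.25), and after quantile normalization (-1.24). Dusp6 lost its call without any 1 of the double mutant libraries (-1.91, -2.04 and -2.04), leukemic 2 (-1.45) or leukemic 3 (-2.06). Dusp2, a phosphatase gene, fell by 3.34 ± 0.71 and kept its call without each library. With only the compared groups in the fit 741 genes were called, and Hbb-bs, Hba-a1, Hlf, Ccne1, Spry2, Dusp6 and Dusp2 were not. Fosb (-5.78) and Mmrn1 (-3.34) lost their calls without leukemic 2 (-5.1 and -2.29). Other rises were Mt2 (6.45 ± 0.82), Abcg4 (6.23 ± 0.97) and Col5a1 (6.17 ± 0.81), and other falls Mmp2 (-4.49 ± 0.75) and Klk8 (-3.61 ± 0.58). In all 1259 of the 13927 tested genes rose and 2123 fell, 37.2% of the called genes higher, with 5383 at an unadjusted p below 0.05. That share was 21.2% after scaling by total counts (785 and 2919), 48.4% after quantile normalization (1204 and 1285), 53.8% after median centring (1735 and 1488), 49.2% after the GC and length correction (1731 and 1785) and 50.3% with the stricter filter (952 and 941). The count was 1685 without double mutant 2, 1568 without double mutant 3, 5295 without leukemic 1, 1185 without leukemic 2 and 1804 without leukemic 3. Over all groups together the F test called 6124 genes, 3881 without Tet2-/- 1, 3966 without Tet2-/- 3 and 3968 without leukemic 3.

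**Figure D2:**
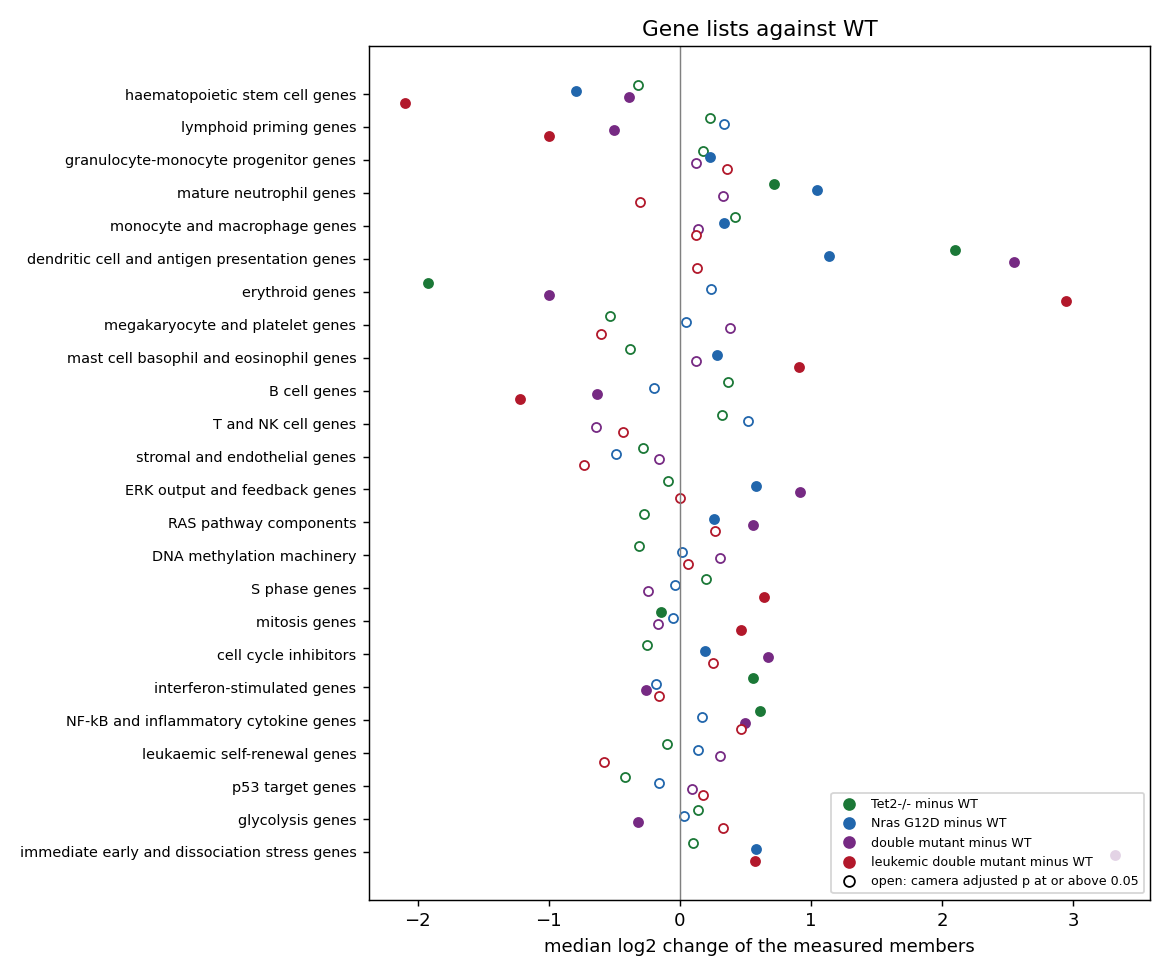
Median log2 change of each of the 24 gene lists against WT for the 4 mutant groups, where filled points have a camera adjusted p below 0.05 (none does with an estimated correlation). Erythroid genes lie at 2.95 in the leukemic double mutant and immediate early genes at 3.32 in the double mutant.

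A set of genes was called in both Tet2-/- and the double mutant. The overlap was 23 genes with the same direction, 14 higher and 9 lower. Independent lists of these lengths share 0.07 and 0.03. In 100 simulations of unchanged groups that share their WT libraries, the top genes of each comparison, in lists of these lengths, shared 6.27 on average and at most 13. This overlap was 3 without WT 1, 5 without WT 2 or WT 3, 42, 35 and 9 without Tet2-/- 1, 2 and 3, 7 without double mutant 2 and 8 without double mutant 3. Between the double mutant and the leukemic double mutant 39 genes were shared, 22 higher and 17 lower, with 1 in opposite directions, against 7.35 and 3.76 for independent lists and a simulated mean of 63.18 (highest 74), which lies above the observed overlap. That overlap was 2, 17 and 3 without WT 1, 2 and 3, 580 without double mutant 1, 6 without double mutant 2 or 3, and 23 without leukemic 3. Between Tet2-/- and the leukemic double mutant 10 were shared, 2 higher and 8 lower, with 1 opposite, against 1.62 and 2.37 for independent lists and a simulated mean of 24.19 (highest 30), again above the observed one. There it was 1 without any 1 of the WT libraries, 144 without Tet2-/- 2, 3 without Tet2-/- 3, 21 without leukemic 1 and 19 without leukemic 2. For the 2 overlaps with the leukemic double mutant, the simulations with shared WT libraries alone gave more genes than were observed. The excess of these overlaps over independent lists therefore does not show a common change. Part of the excess of the 23 genes may also come from the shared WT libraries. The WT libraries are too few to be divided into 2 sets of at least 2. Every overlap with Nras(G12D) was 0, since limma called no gene there. Without Nras(G12D) 3 it was 3 with Tet2-/-, 3 with the double mutant and 4 with the leukemic double mutant, and without Tet2-/- 1 it was 2 with Tet2-/-.

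Among the 23 genes, Rpl34, its near-identical copies Rpl34-ps1 and Gm5900, and Gbp2b did not pass the threshold in the libraries labelled leukemic. Rpl34 (chromosome 3, 130726831 to 130730398) was at 132 ± 20.3 CPM in WT, 47.7 ± 9.57 in Tet2-/-, 51.8 ± 5.5 in the double mutant, 185 ± 53.1 in Nras(G12D) and 177 ± 30.5 in the leukemic double mutant. Rpl34-ps1 and Gm5900, chosen after their values were seen, rose by a log2 of 4.32 and 4.09 in Tet2-/- and by 4.2 and 3.55 in the double mutant, and were at 0.43 and -0.32 in the leukemic double mutant. How their reads and those of Rpl34 were divided by the counting is not known. Gbp2b (chromosome 3, 142594847 to 142619179) was at 27.2 ± 8.38 CPM in the double mutant and at 0.257, 5.81 and 0.327 in the leukemic libraries. Outside the 23, Alpk1 (chromosome 3, 127670310 to 127780527) was called in Tet2-/- but not in the double mutant (adjusted p = 0.0676, limma). It was at 15.6 ± 2.41 CPM in WT, 79 ± 31 in Tet2-/-, 54.4 ± 7.82 in the double mutant and 7.02 ± 2.39 in the leukemic double mutant. Ifi44l (chromosome 3, 151758737 to 151762892) was at 73.6, 0.0151 and 62.6 CPM in the Tet2-/- libraries, the middle value being 0 counts, and 22.3, 21.6 and 38.2 in the double mutant, and passed against WT in neither. With 3 counts over the leukemic libraries it was at 0.0498 ± 0.0334 CPM there (limma, adjusted p = 0.0114 against the double mutant), a call lost with the stricter filter and with voom weights.

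**Figure D3:**
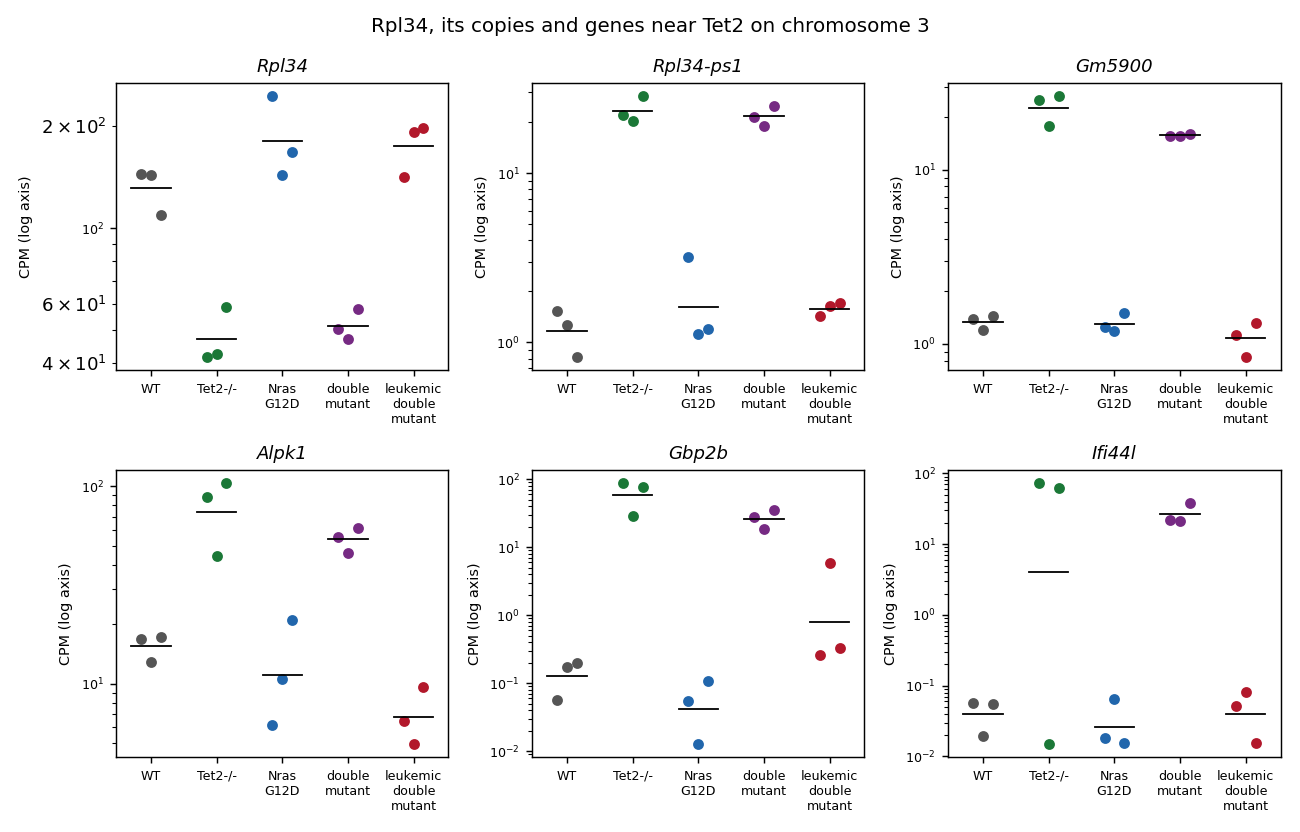
CPM (log axis) of Rpl34, its copies Rpl34-ps1 and Gm5900, and Alpk1, Gbp2b and Ifi44l in each library, where points are libraries and black lines geometric means of 3. Rpl34-ps1 was at 1.42 to 1.7 CPM in the leukemic libraries and at 20.4 to 28.6 in Tet2-/-, and Ifi44l was at 0.0151 CPM in Tet2-/- library 2.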

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

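The tests of heat shock genes, of ERK output genes, of library medians and of the genes near Tet2 on chromosome 3 were chosen only after those results were seen. The GC and length tests and the splits of the samples were set before their results were seen, except that the block was joined to the GC and length correction afterwards.

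Gene lists, 6 in all, differed in the interaction, a test of whether the double mutant departs from the sum of the single mutants' changes, by camera. The medians were -1.41 for mature neutrophil genes (camera adjusted p = 0.00134), -0.67 for monocyte and macrophage genes (0.0332), -1.39 for T and NK cell genes (0.00124), -0.71 for interferon-stimulated genes (0.000346), -0.3 for glycolysis genes (0.0127) and 2.12 for immediate early genes (0.00017). With an estimated correlation every one of these had an adjusted p = 0.771, and with fry the adjusted p ran from 0.163 to 0.498. No member of any of them passed over all genes in the interaction, and adjusted over the list alone 7 immediate early genes were higher and 5 glycolysis genes lower, with 0 in the other lists. The neutrophil median was 0.03 without Nras(G12D) 2, where the call was lost, and -2.32 without Nras(G12D) 3. Glycolysis genes lost their call without Nras(G12D) 2 (-0.15) and had a median of -0.55 without Nras(G12D) 1. The monocyte call was lost without WT 2 (-0.62), Tet2-/- 3 (-0.32), Nras(G12D) 1 (-0.68) or Nras(G12D) 2 (-0.57).

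For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real count was 32 for Tet2-/- against WT (1 of 10 splits as large, highest other 0), 0 for Nras(G12D) (10 of 10, highest other 0), 95 for the double mutant (1, highest other 0) and 3443 for the leukemic double mutant (1, highest other 0). It was 3382 for leukemic against non-leukemic double mutants (1, highest other 1), 3999 for the double mutant against Tet2-/- (1, highest other 1) and 11 for the double mutant against Nras(G12D) (2, highest other 367). That last split set Nras(G12D) 1 with double mutants 2 and 3, which points to a structure among these samples other than the groups. For the double mutant against Tet2-/-, the other splits that part every same-numbered pair, 4 with the real one, reached 0 genes and the remaining 6 reached 1. For the interaction the real count was 0, which makes each of the 100 drawn splits as large whatever the data, so they decide nothing. Their highest count was 1464, but redrawn labels can turn a difference between groups into this contrast. For the F test over 5 groups 1 of 100 gave as many as 6124, the real one, with 1865 as the highest other. That argues against a chance assignment of these 15 libraries to groups. The splits treat the libraries as independent, which the labels do not state.

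Many genes differed between the double mutant and Tet2-/-, with 70.2% of them higher, but 45.9% after quantile normalization (2327 and 2746) and 33.3% after median centring (2020 and 4039). Changes followed GC content in this comparison across genes (Spearman 0.27), where genes are not independent replicates. The coefficient was -0.31 for Tet2-/- against WT, 0.25 for the interaction and 0.1 for the double mutant against WT. The trend was thus stronger in the comparisons that hold Tet2-/-. After the GC and length correction 4116 genes were called between the double mutant and Tet2-/-, against 3999 before. That argues against the trend as the whole cause of the count, although the share of rises was 56.5%. With the replicate number as a block as well the counts were 4083 and 3859. Median centring and quantile normalization gave 6059 and 5073 genes. The median log2 change over all tested genes was 0 before centring, so centring itself shifts the changes and cannot decide whether library medians cause the count. The share of rises depends on the scaling, and the difference in genotype that the design names stays open.

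Immediate early genes were higher in the double mutant than in WT. After the GC and length correction their median was 2.66 against 3.32, which argues against that bias as the whole cause. Stress in handling or dissociation, which also induces these genes, could not be excluded: 5 heat shock genes had a median of 0.44 and went both ways. Hspa1a was at 3.75 and Hspa1b at 3.32, while Hspa8 was at -0.38 and Hsph1 at -0.71. A candidate explanation from the design is ERK signalling in the double mutant. The 19 ERK output genes outside the immediate early list had a median of 0.9, with Dusp2 at 2.24 and Myc at -0.01 and none past the threshold alone. Their rise cannot separate ERK signalling from handling stress, since nothing here shows that handling leaves these genes unchanged. Both lists were lower in the leukemic double mutant than in the double mutant, under the same genotype label. Stress and ERK signalling may both contribute, and no label gives the time or order of the sorts.

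Rpl34 and Gbp2b, near Tet2 on chromosome 3, passed the threshold against WT in Tet2-/- and the double mutant and did not pass it in the libraries labelled leukemic, where Gbp2b was at 0.257, 5.81 and 0.327 CPM, and 14 of the 23 shared calls, these 2 included, did not pass there. A strain haplotype kept around the targeted locus stays open: without these genes, which prompted the test, 0 of 19 shared calls with a position lay within 20 Mb of Tet2 against 155 of 13556 other genes (Fisher's exact test, two-sided, p = 1, odds ratio 0, 95% interval 0 to 18.7), too few to decide. Reads shared between Rpl34 and its copies stay open for Rpl34: the sum of the 3 genes changed by -45.7 ± 12.9 CPM, but counting that drops reads fitting several copies would lower it too. Cells like those of WT making up leukemic libraries 2 and 3 are argued against by stem cell genes, whose median lay at -2.31 or lower from WT (SD 0.43 within groups), but for leukemic library 1 (-0.26) they stay open, where Ddx3y was at 157 CPM against at most 0.476 in WT and Xist at 56.8 against 366 to 490. Leukemic animals without that haplotype, or a wrong label, cannot be told apart from the rest, and no genotype reads decide it. The leukemic means of 2 of 3 genes, Rpl34 and Rpl34-ps1, lay inside the range of the WT and Nras(G12D) libraries. Gm5900 was at 1.12, 0.84 and 1.32 CPM in the leukemic libraries against 1.18 to 1.5 in WT and Nras(G12D). In Tet2-/- and the double mutant it was at 15.51 to 26.5, so no leukemic library had the Tet2-/- levels of these genes. What BMT marks in the descriptions of the leukemic samples was not tested.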

How the results depend on the processing

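The fits with voom weights, an added count of 0.1, sample quality weights, weights gene by gene, total-count or median-of-ratios scaling, the Y-linked covariate and the GC and length correction were chosen after the data were seen, as were all alternatives for the overlaps but the minimum log2 change of 1. The rest were set before, and the cause was not tested for any difference below except where fewer genes or samples enter by construction.

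Of counts under alternatives other than leaving out a library, 107 stayed within 1.5 times and 45 did not. Tet2-/- against WT gave 53 genes with no filter, 8 with the stricter filter, 57 with only the compared groups, 713 with the replicate number as a block (93 higher and 620 lower), 144 after quantile normalization and 89 after median centring. The double mutant against WT gave 21 with the stricter filter, 574 with only the compared groups, 213 after quantile normalization and 396 with the Y-linked covariate. Leukemic against WT and against the double mutant gave 2145 and 1893 with the stricter filter, and the latter 741 with only the compared groups. The double mutant against Nras(G12D) gave 6 with the stricter filter, 5 with only the compared groups, 25 after quantile normalization and 17 after median centring, and against Tet2-/- 6059 after median centring. Nras(G12D) against WT gave 1 with only the compared groups, 1 with array weights and 2 with voom weights. Of 30 same-numbered pairs of libraries 12 had a correlation over 0.1 (median 0.07), and for 7 of 15 libraries the best partner had its number. Between Tet2-/- and the double mutant all 3 pairs did, unlike between any other groups, and the block gave 3859 genes there against 3999. It ended no call of a named gene or list in that comparison, while Fcer1a, Blnk and Klrb1c, which did not pass without it, did with it.

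Weights per library moved most counts. Array weights, whose estimate stopped before convergence with a weight of 134.74 on leukemic 3, gave 7264 for Tet2-/-, 3807 for the double mutant and 10442 for leukemic against WT, 9695 for leukemic against non-leukemic, 9018 against Tet2-/-, 181 against Nras(G12D), 6639 for the interaction and 12968 for any group. In the same order voom with sample quality weights gave 6938, 3660, 8426, 7900, 8802, 22, 5917 and 12366, and array weights gene by gene 7058, 3613, 8334, 7767, 8793, 23, 5961 and 12359. Tet2-/- 2 had weights of 0.22 to 0.28.

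Leaving out each library in turn gave 5 to 2235 genes for Tet2-/-, 0 to 5 for Nras(G12D), 6 to 992 for the double mutant and 1356 to 5251 for leukemic against WT. It gave 1185 to 5295 for leukemic against non-leukemic, 1258 to 5243 against Tet2-/-, 9 to 114 against Nras(G12D), 0 to 1692 for the interaction and 3881 to 7874 for any group. The double mutant against Tet2-/- reversed for Zfpm1 under the GC and length correction, at -0.43 against 2.68 (adjusted p = 0.533, or 0.536 with the block as well). The mature neutrophil list reversed without Nras(G12D) 2, at -0.42 for Nras(G12D) against WT (-0.42 to 1.81 over the libraries left out) and at 0.86 for the double mutant against Nras(G12D) (-1.57 to 0.86). Of 319 called values of named genes 302 kept their call under the GC and length correction, 295 after quantile normalization and 305 with voom weights. Of the 72 list tests that camera called, 63 kept their call under the GC and length correction. Median centring shifted libraries by up to 0.39 (Tet2-/- 1) and -0.32 (double mutant 2), and total-count scaling by up to -0.3 (leukemic 2). With an added count of 0.1 every count of changed genes stayed within 1.5 times and 314 of the 319 calls were kept. A count test set before the data were examined was not run, and voom weights used the recovered counts. Counting depth limits genes near 0.0775 to 0.127 CPM.

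A minimum log2 change of 1 left each of the 6 overlaps within 1.5 times, 3 of them at 0. It removed none of the 32 calls of Tet2-/- or the 95 of the double mutant, and Nras(G12D) had none. That check could therefore hardly move the overlaps. Other alternatives moved them. Tet2-/- with the double mutant shared 5 genes with the stricter filter, 47 with the block, 63 after quantile normalization, 37 after median centring and 40 with the Y-linked covariate. Tet2-/- with leukemic shared 20 with no filter, 1 with the stricter filter, 42 with the block, 43 after quantile normalization, 23 after median centring and 6 with an added count of 0.1. The double mutant with leukemic shared 8 with the stricter filter, 109 after quantile normalization and 225 with the Y-linked covariate. In this order the overlaps were 520, 1860 and 2190 with array weights, 477, 1396 and 1834 with sample quality weights, and 479, 1382 and 1787 with weights gene by gene. Nras(G12D) shared 1 gene each with Tet2-/- and the double mutant with array weights, and 2, 2 and 1 with Tet2-/-, the double mutant and leukemic with voom weights. Leaving out each library in turn gave 3 to 42, 1 to 144 and 2 to 580 for the first 3 overlaps, and 0 to 3, 0 to 3 and 0 to 4 for Nras(G12D) with Tet2-/-, the double mutant and leukemic.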

Other observations

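The gene lists below were set before the data were examined; the description of leukemic library 1 was chosen after its values were seen.

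Leukemic library 1 stood apart from the other leukemic libraries in genes of several groups. Rhag was at 85.3 CPM there against 1270 and 325, Gata1 at 63.8 against 445 and 248, and Cd34, a progenitor surface protein gene, at 1100 against 129 and 316. Mitosis genes rose in 3 of 23 in leukemic against non-leukemic double mutants, or 1 adjusted over the list alone, with 22 above 0 (median 0.57, camera adjusted p = 0.000695, and adjusted p = 0.771 with an estimated correlation). Leukaemic self-renewal genes fell in 7 of 28 and rose in 1, or 8 and 1 adjusted over the list alone (median -0.89, camera adjusted p = 0.0298, and adjusted p = 0.809 with an estimated correlation), and lost the call without leukemic 2 (-0.35).

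Dendritic cell and antigen presentation genes had a median of 1.1 in the double mutant over Nras(G12D), with 15 of 16 above 0, none past the threshold and 1 higher adjusted over the list alone (camera adjusted p = 0.000193, and adjusted p = 0.771 with an estimated correlation). Their median was 1.75 without Nras(G12D) 1 and 0.37 without Nras(G12D) 2, where the call was lost. Lymphoid priming genes fell in 5 of 16 and rose in 1 in the leukemic double mutant against WT by both counts (median -1, camera adjusted p = 0.0151, and adjusted p = 0.771 with an estimated correlation), and lost the call without leukemic 2 (-0.48).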
